A study of Homo sapiens with 4 samples.

How the data were processed

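Gene expression was measured in 4 RNA samples of a human prostate cancer cell line that the labels call DU154. The labels put 2 arrays in a wild type group and 2 in a group named mH2A1.2_KO, described as depleted of mH2A1.2, a splice form of the histone variant macroH2A1. How the depletion was made is not given in the sources used here. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

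Per the labels' protocols, total RNA was column-purified and converted to biotinylated cRNA for single-colour Illumina bead arrays, and the submitters' processing notes name GenomeStudio. The authors deposited a table of raw intensity per probe for 47230 probes, on a linear scale without visible background subtraction. The same deposited table gives a detection p-value per probe and array, in steps of 1 in 770. The authors also deposited normalized values that lie on a log2 scale, with 43957 rows of which 43893 hold values and 64 are blank, and the normalization behind them is not given in the sources used here. Their medians were 6.44 and 6.43 in the wild type arrays and 6.44 and 6.43 in the mH2A1.2_KO arrays. The 3273 probes of the raw table that are absent from the normalized table were left out of every test on the normalized values. They could enter the alternatives computed from the raw signals.

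The 2 deposited tables disagree on 2 arrays. After centring each probe over 8096 probes with a mean log2 signal above 8.5, each raw array followed 1 normalized column with a correlation of at least 0.997, and the next highest correlation was 0.0235. The array that the raw table's header gives to wild type replicate 2 was the one that the normalized table gives to mH2A1.2_KO replicate 1, and the reverse. The normalized table names its columns by sample and was taken for the groups, a choice made before any group difference was computed. The planned processing was limma's neqc on the raw signals. The normalized values were used in its place, with quantile normalization across the 4 arrays, and neqc with each raw array named by the normalized column it followed became an alternative chosen after seeing the data. Grouping by the raw table's header, and the difference between the 2 arrays that both tables place alike (wild type replicate 1 and mH2A1.2_KO replicate 2), were also added after seeing the data.

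Probes were named through the platform annotation: 29471 of the probes with values had 1 gene symbol, 0 had several and 14422 were unnamed here. Probes with a detection p-value under 0.01 on at least 2 of the 4 arrays were kept, which left 16950. A gene with several kept probes, of which there were 2585, was represented by the probe with the highest mean. This gave 13786 features, 10673 of them named. Arrays of this kind carry no read depth, and their number limits the precision: 38.9% and 35.4% of probes were detected on the wild type arrays and 35.8% and 35.9% on the mH2A1.2_KO arrays.

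Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 2 residual degrees of freedom plus 4.1 prior degrees of freedom), with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. Standard errors (SE) are the moderated ones of this fit. MACROH2A1 probes were tested in a fit of all 16950 detected probes and adjusted also over the gene's own detected probes. There were 30 gene lists fixed before the data were examined, of which the 25 with at least 5 tested members were tested with limma's camera at its preset correlation of 0.01. The other 5 hold markers of other cells and are given by member. Camera with an estimated correlation and fry were alternatives. A gene not above background on either array of a group has a bound, computed against the lowest signal among detected probes of each array of that group or the probe's own signal if higher.

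The rule for named genes was fixed before the data were examined. It takes every probe of MACROH2A1, MACROH2A2, CBX5, H1-2, LTB, TNFSF11 and TNFRSF11B. It adds the 12 highest and 12 lowest named genes whose arrays do not overlap between groups, stated as not past the test where they are not, and up to 4 members per list with the largest difference. The first 2 members per list are named here, a narrowing set after values were seen. The rule also took each member past the test where there were 4 or fewer. Here members past the test adjusted over the list alone are named where a direction has 5 or fewer of them. Of these IL32, CXCL8, LIF, VEGFA, IER3 and DUSP1 fall outside the rule in the list concerned and were chosen after their values were seen.

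The fit was tested on simulated data with the real spread, over 13786 features. It recovered 32% of 50 features changed by 1 on the log2 scale, 96% of those changed by 2 and 100% of those changed by 3 or by 4, and 9 of 173 calls were unchanged features. All sizes of change were planted in the same run, and many true changes ease the Benjamini-Hochberg threshold. These shares therefore do not give the power of a comparison in which few features change. For a shift of 0.5 in 37 simulated list members, camera gave an adjusted p of 5.1e-20 and called 0 of 24 other lists. With an estimated correlation the same simulated shift gave an adjusted p of 0.375, and fry gave 0.508. In this simulated run, with 2 arrays per group, neither reached the threshold. The simulation drew features independently, so it does not test camera on correlated genes.

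Alternatives varied the background correction, the offset, the normalization (median scaling, cyclic loess, none beyond the deposited values), the detection filter, the handling of several probes, the variance trend, a replicate block, the threshold and the test of lists, and left out each array in turn. Those on the background correction, the offset, median scaling, cyclic loess and neqc were computed from the raw signals. They tested 14426 features in place of 13786.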

Results

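The data were 4 bead arrays of a prostate cancer cell line, 2 of wild type cells and 2 of cells labelled mH2A1.2_KO. The series title names osteoclast formation induced by prostate cancer cells and the chromatin proteins HP1a and H1.2, so the comparison asks which genes differ when this macroH2A1 form is depleted. The number of probes above background was 18377 and 16727 on the wild type arrays and 16921 and 16962 on the mH2A1.2_KO arrays. Median raw signals were 141.1 and 139.8 in wild type and 140.6 and 142.4 in mH2A1.2_KO. Across genes, the correlation of log2 values was 0.9747 between the wild type arrays and 0.9873 between the mH2A1.2_KO arrays, and between arrays of different groups it ranged from 0.9729 to 0.9865. The SD of the difference between arrays was 0.402 in wild type and 0.284 in mH2A1.2_KO.

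MACROH2A1, the gene of the depleted histone variant, was lower in both mH2A1.2_KO arrays. Its brightest probe measured 13.02 and 12.91 on the log2 scale in wild type and 11.97 and 11.83 in mH2A1.2_KO, a difference of -1.07 ± 0.16 (SE, 2 arrays per group) or 2.09-fold. A second probe, annotated to another transcript of the gene, measured 10.25 and 10.46 against 9.41 and 9.26, a difference of -1.02 ± 0.17 or 2.02-fold. The third probe, annotated to the same transcript as the second, differed the other way, with 8.86 and 8.41 against 9.49 and 9.03, a difference of 0.62 ± 0.24. The fourth probe was not above background on any array.

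Adjusted over the gene's own detected probes, limma gave an adjusted p of 0.00119 for each of the first 2 probes and 0.0377 for the third. Adjusted over all detected probes, the values were 0.246, 0.271 and 0.626. The probe annotation does not say which probe reads mH2A1.2 alone, so these probes measure transcripts of the gene and not the splice form. Under the grouping of the raw table's header the brightest probe differed by -0.12, with an adjusted p of 0.953 over the gene's probes, and array names here follow the normalized table.

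MACROH2A2, which encodes the related variant macroH2A2, measured 10.90 and 10.82 in wild type and 10.16 and 10.40 in mH2A1.2_KO, a difference of -0.58 ± 0.17 that did not pass the test (adjusted p = 0.487). H1-2, the linker histone H1.2, measured 0.97 ± 0.28 higher and CBX5, the gene of HP1a, 0.36 ± 0.15 higher on the log2 scale, also not past the test. LTB, a cytokine of the tumour necrosis factor family, was read by 2 probes, which measured 1.75 ± 0.46 and 1.41 ± 0.51 higher. Its brighter probe gave 8.62 and 8.48 in wild type against 11.07 and 9.53 in mH2A1.2_KO. TNFSF11, the osteoclast differentiation factor RANKL, and TNFRSF11B, its decoy receptor osteoprotegerin, were not above background on any array.

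**Figure D1:**
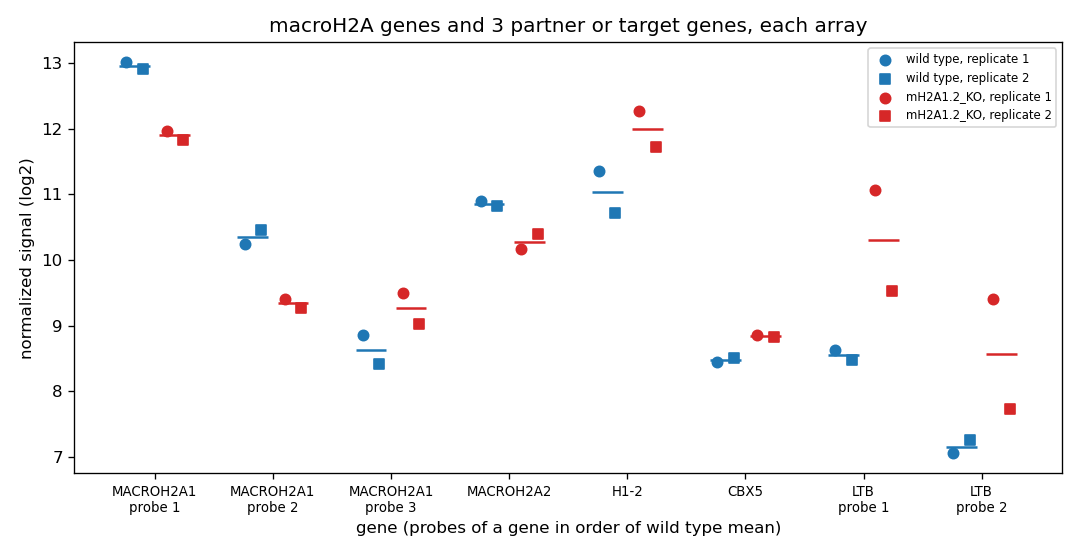
Normalized log2 signal (vertical axis) of each detected probe of MACROH2A1, MACROH2A2, H1-2, CBX5 and LTB (horizontal axis). Points are arrays and lines are means of 2 arrays per group; the first MACROH2A1 probe lies near 13 in wild type and near 11.9 in mH2A1.2_KO, while the third lies higher in mH2A1.2_KO.

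MUC1, a membrane mucin of epithelial cells, had the largest difference of any named gene whose arrays did not overlap between groups. It measured 8.61 and 8.96 in wild type and 10.89 and 11.08 in mH2A1.2_KO, 2.20 ± 0.19 higher or 4.59-fold. PLAAT4, a phospholipase and acyltransferase induced by retinoids, measured 1.72 ± 0.15 higher. KRT8, a keratin of simple epithelia, measured 1.68 ± 0.18 higher. DUSP6, a phosphatase that dephosphorylates ERK kinases, measured -1.25 ± 0.16 and CTSC, the protease cathepsin C, -1.22 ± 0.17 relative to wild type. The second probe of DUSP6 measured -0.65, and the 4 detected probes of CTSC ran from -1.22 to -0.30.

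None of these genes passed the test over all features. limma called 0 of 13786 features at an adjusted p under 0.05, the lowest adjusted p was 0.183 (MUC1 and PLAAT4), and 1065 features had an unadjusted p under 0.05, 603 higher and 462 lower in mH2A1.2_KO, where 689 would be expected with no change. That number was 383 without mH2A1.2_KO replicate 1, 486 without mH2A1.2_KO replicate 2, 2026 without wild type replicate 2 and 1929 when the arrays were split by replicate number. At least a 2-fold difference was measured for 109 features, 80 higher and 29 lower. The number higher was 119 of 225 without wild type replicate 2, 58 of 102 without mH2A1.2_KO replicate 1 and 15 of 87 under the grouping of the raw table's header. Arrays did not overlap between groups for 4936 features or 35.8%, where chance gives 33.3%. The count of 0 did not hold when a wild type array was left out. Nor did it hold with a replicate block, which takes same-numbered arrays as pairs. The labels do not say that the numbers pair the arrays, and the counts are given below with the other alternatives. Under the grouping of the raw table's header the sign turned for 36 of 74 named genes and the direction of the list test for 16 of 25 gene lists. That grouping is the split by replicate number, which is independent by design of the split used. Signs can turn often there whatever the group differences, so these counts do not measure how firm those are.

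The other genes among the 12 highest were MARCHF4 (1.86), LTB (1.75), S100A3 (1.66), the small nucleolar RNA SNORA28 (1.62), IFIT3 (1.56, above background on 1 of 2 wild type arrays), the cytidine deaminase CDA (1.53), IFIT1 (1.43), IFIT2 (1.40) and the insulin-like growth factor binding protein IGFBP4 (1.39). The other genes among the 12 lowest were GLB1, the lysosomal beta-galactosidase (-1.27), BTBD10 (-1.26), SLC25A4, a mitochondrial ADP/ATP carrier (-1.24), CLDN10, a tight junction claudin (-1.24), the transcription factor EGR1 (-1.22), TMSB15A (-1.20), NPTX2 (-1.18), RPN2 (-1.17), the lysosomal protease LGMN (-1.16) and ITPKA (-1.16). Each number is the log2 difference, mH2A1.2_KO minus wild type. Their adjusted p-values ranged from 0.231 to 0.647. When 1 array was left out the difference ran from 0.98 to 2.52 for LTB, 0.93 to 1.92 for IFIT1, 0.77 to 2.01 for IGFBP4, -2.04 to -0.39 for EGR1, -1.67 to -0.73 for TMSB15A, -1.84 to -0.51 for NPTX2 and -1.64 to -0.68 for LGMN. The 3 probes of IFIT3 ran from 0.67 to 1.56, and the second probe of CLDN10 measured -0.71.

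**Figure D2:**
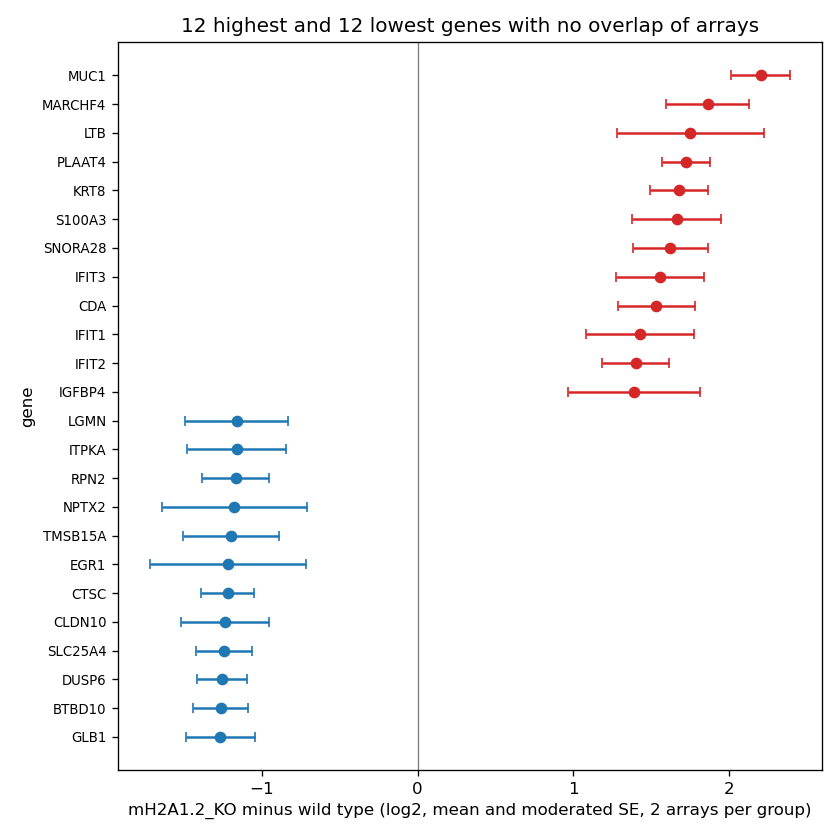
Log2 difference, mH2A1.2_KO minus wild type (horizontal axis), of the 12 highest and 12 lowest named genes with no overlap of arrays (vertical axis). Points are differences of means of 2 arrays per group and bars the moderated SE; none passed the test over all features, and the differences run from 2.20 for MUC1 to -1.27 for GLB1.

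Genes of the type I interferon response measured higher in mH2A1.2_KO. Of 37 tested members 34 were higher, with a median log2 difference of 0.46, and 26 of the 34 had arrays that did not overlap, where chance gives 33.3% over both directions. IFIT3 and IFIT1, antiviral proteins with tetratricopeptide repeats, measured 1.56 ± 0.28 and 1.43 ± 0.34 higher. Adjusted over the list alone 10 members passed, all higher, and 0 passed over all features. camera called the list (adjusted p = 2.03e-15), and the adjusted p was 0.329 with an estimated correlation.

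Replication-dependent core histones, which package newly replicated DNA, measured higher for 14 of 16 members, with a median of 0.62. H2AC20 measured 1.37 ± 0.21 and H2AC6 1.31 ± 0.39 higher. The median was 0.35 without mH2A1.2_KO replicate 1, 0.35 with no detection filter and 0.37 between wild type replicate 1 and mH2A1.2_KO replicate 2, the 2 arrays that both tables place alike. Adjusted over the list alone 7 members passed, all higher. camera gave an adjusted p of 1.02e-09, and adjusted p = 0.628 with an estimated correlation. Genes of DNA replication and S phase measured lower for 39 of 47 members, with a median of -0.17, and RRM2, a subunit of ribonucleotide reductase, measured -1.05 ± 0.36 and MCM10 -0.67 ± 0.24. The adjusted p was 0.000198, and adjusted p = 0.693 with an estimated correlation, and 0 members passed adjusted over the list alone. Arrays did not overlap between groups for 11 lower members and 1 higher of the 47, where they did not for 35.8% of all features. For replicate 1 minus replicate 2 the median of this list was -0.36. Without wild type replicate 2 the median was -0.0048 and the call was lost, as it was without mH2A1.2_KO replicate 1 (adjusted p = 0.238). The median was -0.38 without wild type replicate 1, and between wild type replicate 1 and mH2A1.2_KO replicate 2 it was 0.14, in the other direction.

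Epithelial adhesion and keratin genes measured higher for 18 of 21 members, with a median of 0.43, which was 0.24 without wild type replicate 2, 0.17 with no detection filter and 0.24 between the 2 arrays that both tables place alike. KRT8, KRT19 (1.24 ± 0.16) and KRT7 (0.95 ± 0.18), all keratins of simple epithelia, were the 3 members past the test adjusted over the list alone. camera gave an adjusted p of 1.42e-07, and adjusted p = 0.329 with an estimated correlation. Mesenchymal genes were not called (adjusted p = 0.211, median 0.16, which was -0.047 without mH2A1.2_KO replicate 1 and 0.058 without wild type replicate 2). In that list CCN2, a matricellular growth factor, measured -1.02 ± 0.18 and AXL, a receptor tyrosine kinase, 0.83 ± 0.17, the 2 members past the test adjusted over the list alone.

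Cholesterol biosynthesis genes measured higher for 22 of 24 members, with a median of 0.30, which was 0.46 without mH2A1.2_KO replicate 2 and 0.16 between the 2 arrays that both tables place alike. The 2 largest differences were MSMO1 (0.76 ± 0.20), a sterol oxidase whose 3 detected probes ran from -0.01 to 0.76, and ELOVL6 (0.58 ± 0.18), a fatty acid elongase. The adjusted p was 1.64e-06, and adjusted p = 0.628 with an estimated correlation, with 0 members past the test adjusted over the list alone. NRF2 targets and metallothioneins, which answer oxidants and metals, measured higher for 22 of 27 members with a median of 0.22, which was 0.13 without wild type replicate 2. AKR1C2, a ketosteroid reductase, measured 1.30 ± 0.15 higher and was the 1 member past the test adjusted over the list alone, and NQO1, a quinone reductase, measured 1.29 ± 0.30 higher, with 0.48 for its second probe. The adjusted p was 0.000205, and adjusted p = 0.329 with an estimated correlation.

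Immediate early genes, which respond first to growth factor signals, measured lower for 17 of 28 members, with a median of -0.21, which was -0.39 without mH2A1.2_KO replicate 1, -0.095 for members detected on all 4 arrays and -0.36 between the 2 arrays that both tables place alike. DUSP6 (-1.25 ± 0.16) and EGR1 (-1.22 ± 0.50) differed most, and EGR1 measured -0.39 without mH2A1.2_KO replicate 1 and -2.04 without mH2A1.2_KO replicate 2. Adjusted over the list alone 9 members passed lower and 1 higher, the phosphatase DUSP1 (0.95 ± 0.17). The adjusted p was 0.000205, and adjusted p = 0.329 with an estimated correlation.

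Secreted factors that act on osteoclasts, the subject of the series title, went both ways. Of 30 tested members 16 were higher and 14 lower, and the list was not called (adjusted p = 0.909, median 0.012, while the test's direction was down). Under the grouping of the raw table's header it was called lower (adjusted p = 0.039, median -0.22, and adjusted p = 0.747 with an estimated correlation). Adjusted over the list alone, LTB and IL32 (0.86 ± 0.23) passed higher, and SPP1, CXCL8 (-0.85 ± 0.22), LIF (-0.72 ± 0.18) and VEGFA (-0.64 ± 0.16) passed lower. SPP1, the bone matrix protein osteopontin, was not above background on either mH2A1.2_KO array and was at least 2.09-fold lower there. IL6, a cytokine that stimulates osteoclast formation, measured 1.15 ± 0.68. Its arrays overlapped between the groups, and the range was 0.32 to 1.98 when 1 array was left out. The differences between same-numbered arrays were 1.11 and 1.19, though the labels do not say that the numbers pair the arrays.

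NF-kappaB targets measured higher for 20 of 32 members, with a median of 0.17, or 0.065 with no detection filter (adjusted p = 0.0176, and adjusted p = 0.628 with an estimated correlation). Adjusted over the list alone 6 passed higher, with LTB and CFB (1.35 ± 0.30), complement factor B, differing most, and 2 passed lower, CXCL8 and IER3 (-0.75 ± 0.19). The call was lost without wild type replicate 2 (adjusted p = 0.0764) and without mH2A1.2_KO replicate 1 (adjusted p = 0.192, median 0.059). Antigen presentation genes measured higher for 15 of 20 members with a median of 0.14 (adjusted p = 0.00759, and adjusted p = 0.628 with an estimated correlation). PSMB8 (0.996 ± 0.158) and PSMB9 (0.98 ± 0.19), subunits of the immunoproteasome that are also in the interferon list, were the 2 members past the test adjusted over the list alone. The 4 probes of PSMB8 ran from 0.31 to 1.12, and the second probe of PSMB9 measured 0.33. The median was -0.11 between wild type replicate 1 and mH2A1.2_KO replicate 2, and the call was lost without wild type replicate 2 (adjusted p = 0.939) and without mH2A1.2_KO replicate 1 (adjusted p = 0.0688). It was 0.43 without wild type replicate 1.

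The remaining called lists had 0 members past the test adjusted over the list alone. Hypoxia and glycolysis genes measured higher for 25 of 36 members with a median of 0.20 (adjusted p = 0.0162, and adjusted p = 0.628 with an estimated correlation), while the member that differed most, ANGPTL4, measured -1.11 ± 0.40 (3 probes from -1.11 to -0.40) and GPI, a glycolytic isomerase, 0.74 ± 0.27. Genes of G2 and mitosis measured higher for 35 of 47 members with a median of 0.12 (adjusted p = 0.0162, and adjusted p = 0.693 with an estimated correlation), among them CCNB1 (0.69 ± 0.33) and KIF20A (0.55 ± 0.20). Genes of the unfolded protein response measured lower for 29 of 45 members with a median of -0.10 (adjusted p = 0.0142, and adjusted p = 0.628 with an estimated correlation). In that list ASNS, which makes asparagine, measured -0.71 ± 0.23 and JDP2 0.71 ± 0.16. MYC target and nucleolar genes measured lower for 26 of 30 members with a median of -0.17 (adjusted p = 0.0176, and adjusted p = 0.708 with an estimated correlation). In that list arrays did not overlap between groups for 3 lower members and 1 higher, where they did not for 35.8% of all features. Its median was 0.052 in the first replicate pair and -0.32 in the second. For replicate 1 minus replicate 2 it was -0.48. MYC itself measured -0.63 ± 0.16 and NOP16 -0.52 ± 0.34.

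Each of these 4 calls was lost without at least 1 array. Without wild type replicate 1 the adjusted p was 0.215 for hypoxia and for the unfolded protein response and 0.8 for G2 and mitosis, whose median was then -0.023. Without mH2A1.2_KO replicate 2 it was 0.785, 0.222 and 0.692 for the same lists in that order. For MYC targets it was 0.818 without mH2A1.2_KO replicate 1 and 0.0764 without wild type replicate 2, where the median was 0.15. When an array was left out, the medians ran from 0.095 to 0.27 for hypoxia, -0.023 to 0.26 for G2 and mitosis, -0.18 to -0.05 for the unfolded protein response and -0.44 to 0.15 for MYC targets. In all, camera called 13 of 25 lists, 9 higher and 4 lower. With an estimated correlation 0 were called (lowest adjusted p 0.329), and fry called 0 (lowest adjusted p 0.0552). The estimated correlation was 0.78 for DNA replication, 0.74 for MYC targets, 0.48 for core histones, 0.45 for antigen presentation and 0.44 for G2 and mitosis. It was 0.1 for the interferon response and -0.025 for NRF2 targets. The preset of 0.01 does not allow for the higher values. Lists with an estimated correlation below the preset lost their call too, among them NRF2 targets and immediate early genes (-0.015). In the simulated run a planted shift also missed the threshold by camera with an estimated correlation (adjusted p = 0.375) and by fry (0.508). The 0 calls of these tests therefore cannot show that a list did not differ.

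**Figure D3:**
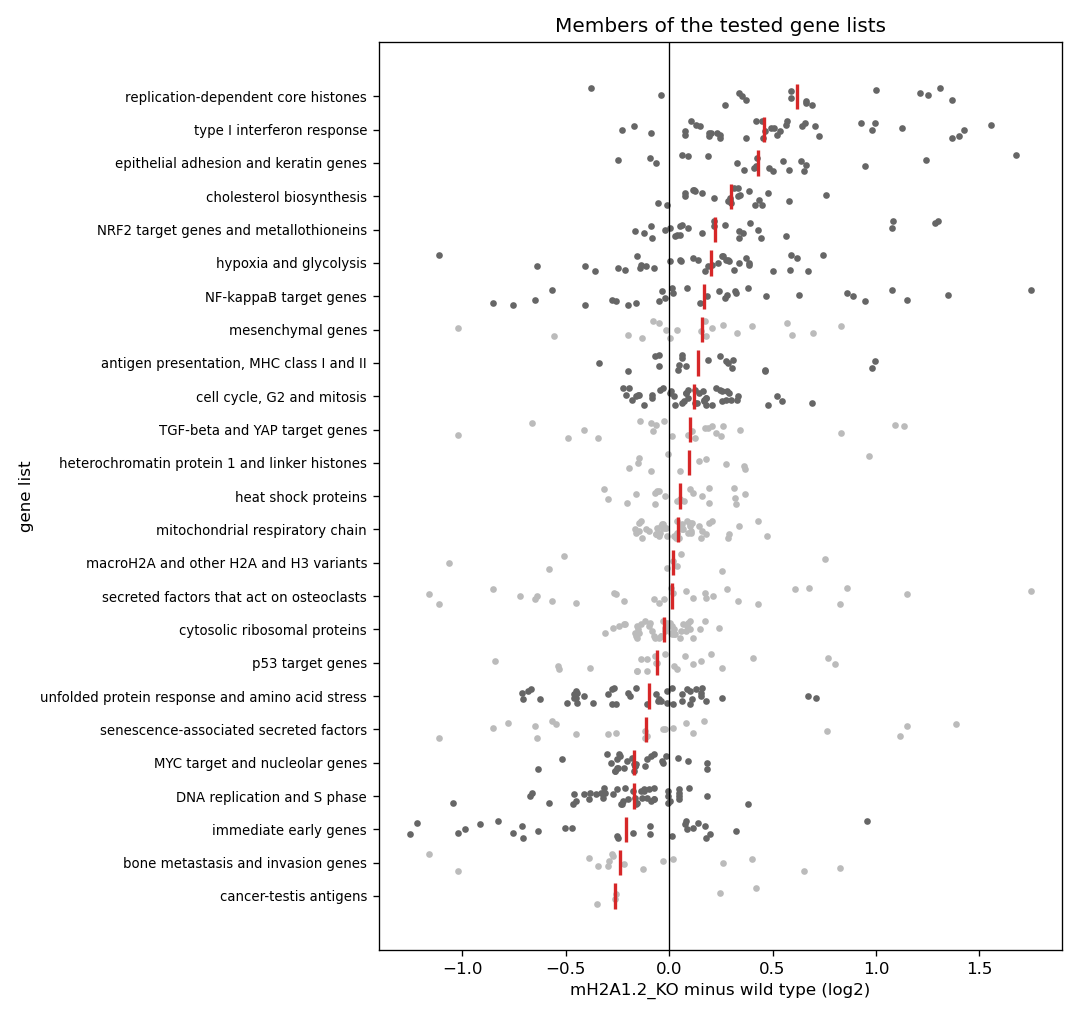
Log2 difference, mH2A1.2_KO minus wild type (horizontal axis), of each tested member of the 25 gene lists (vertical axis). Points are genes, dark in lists past camera at its preset correlation, and red bars are medians, which run from -0.26 for cancer-testis antigens to 0.62 for core histones.

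Lists that were not called held single genes with sizeable differences. In the list of macroH2A and other histone variants (adjusted p = 0.334, median 0.019, test direction down) MACROH2A1 passed adjusted over the list alone, and H2AJ measured 0.75 ± 0.24. Among heterochromatin proteins and linker histones (adjusted p = 0.211, and 0.0311 with no detection filter, median 0.097) H1-2 and LMNB1 (0.37 ± 0.20), a nuclear lamin, differed most. Among bone metastasis and invasion genes (adjusted p = 0.16, median -0.24) SPP1 and CCN2 passed lower adjusted over the list alone. With an estimated correlation camera gave that list an adjusted p of 0.628. Leaving out 1 array changed whether it was called. Its median was -0.28 without mH2A1.2_KO replicate 1, -0.26 without wild type replicate 2 and 0.041 without wild type replicate 1. Among p53 targets (adjusted p = 0.909, median -0.061) CDKN1A, the cell cycle inhibitor p21, passed lower (-0.84 ± 0.17) and PHLDA3 higher (0.77 ± 0.17) adjusted over the list alone, and PLK2 measured 0.80 ± 0.21. Among TGF-beta and YAP targets (adjusted p = 0.41, median 0.10, which was -0.00097 without mH2A1.2_KO replicate 1 and -0.0031 without wild type replicate 2) ANKRD1 (1.14 ± 0.26), F3 (1.09 ± 0.25) and AXL passed higher and CCN2 lower adjusted over the list alone. When 1 array was left out the medians ran from -0.11 to 0.0086 for histone variants, -0.064 to 0.28 for heterochromatin proteins and -0.072 to 0.067 for p53 targets.

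Senescence-associated secreted factors had a median of -0.11 (adjusted p = 0.203, and -0.27 to 0.02 for the median when 1 array was left out), with IGFBP4 at 1.39 ± 0.42 and IL6 the members that differed most. IGFBP4 measured 0.77 without mH2A1.2_KO replicate 1. Heat shock proteins had a median of 0.053 (adjusted p = 0.604, and adjusted p = 0.918 with an estimated correlation). The median ran from -0.098 to 0.20 when 1 array was left out. It was highest without wild type replicate 2, where the list was called higher. In this list DNAJB4 measured 0.37 ± 0.19 and BAG3 0.33 ± 0.18. Cytosolic ribosomal proteins had a median of -0.024 (adjusted p = 0.334), with RPL28 at -0.31 ± 0.21 and RPL8 at -0.27 ± 0.20, whose other detected probe measured 0.23. The list was called lower on the deposited values without further normalization (adjusted p = 0.034). On the values used here camera with an estimated correlation gave it an adjusted p of 0.693. Respiratory chain genes had a median of 0.043 (adjusted p = 0.211), with NDUFA10 at 0.47 ± 0.17 and NDUFB10 at 0.43 ± 0.21. Of the cancer-testis antigens 5 were tested (adjusted p = 0.737), with TKTL1 at 0.42 ± 0.16 and DDX43 at -0.35 ± 0.16.

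Markers of other cells were mostly below background. Of 13 measured markers of androgen-responsive luminal prostate lines 4 were detected, STEAP2 (-0.61, its other probe -0.83), SLC45A3 (-0.54), FKBP5 (-0.26) and PMEPA1 (0.09, 3 probes from -0.09 to 0.09). Of the fibroblast markers 2 of 14 were detected (MFAP5 -0.20 and COL1A1 -0.05), of the leukocyte and osteoclast markers 4 of 20 (CD68 0.36, CD14 0.28, its other probe -0.05, CORO1A 0.25 and CTSK -0.28), of the erythroid and platelet markers 1 of 10 (PPBP 0.10) and of the neuroendocrine markers 1 of 8 (ENO2 0.14). None of these detected genes passed the test adjusted over its own list, where the lowest adjusted p was 0.122 (SLC45A3).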

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

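The tests on which table names the arrays rightly were chosen after the result had been seen. Of the 3273 probes that are in the raw table and not in the normalized one, 327 were above background on all 4 arrays. Above background on both mH2A1.2_KO arrays and on neither wild type array were 16 of them, and 43 showed the opposite. These probes entered no comparison, and their genes were not analysed here.

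The 2 deposited tables give the arrays of wild type replicate 2 and mH2A1.2_KO replicate 1 to each other's sample. If the raw table's header were right, the brightest MACROH2A1 probe would differ by -0.124 between groups, less than the gaps of 1.05 and 1.08 between arrays within those groups. Under the normalized table it differs by -1.07, more than the gaps of 0.106 and 0.143 within its groups. The second probe differed by 0.03 under the header and by -1.02 under the normalized table, and the third by -0.45 and 0.62. For all 3 detected probes the groups overlapped under the header and did not under the normalized table. This argues against the header, provided that depletion changed the transcripts that the probes read, which was not tested. The sample titles end in letters, which the header lists in the order E, G, F and H. Named by the normalized column each follows, the raw columns run E, F, G and H. The header's grouping gave 1929 features at an unadjusted p under 0.05 in limma, against 1065. Arrays within its groups correlated at 0.9814 and 0.9865, against 0.9747 and 0.9873 in the grouping used. That grouping is also the split by replicate number. Differences shared by same-numbered arrays would give such values too, so they cannot decide between the tables.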

How the results depend on the processing

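Of the alternatives, neqc on the raw signals, the header's grouping and the 2 arrays that both tables place alike were chosen after seeing the data. The brightest MACROH2A1 probe stayed lower and past the test over its own gene under every alternative fixed before the data were examined and run for it, with -0.99 to -1.14 when an array was left out. It differed by -0.12 under the header's grouping and by -1.19 between the 2 arrays placed alike. The count of called features was 0 in limma under every alternative but 4: it was 2 with no detection filter (MUC1 and PLAAT4, with 2001 features at an unadjusted p under 0.05), 425 with the replicate block, and 0 to 156 when an array was left out (0 without either mH2A1.2_KO array, 57 without wild type replicate 1, 156 without wild type replicate 2). Leaving out a wild type array leaves the spread to the mH2A1.2_KO pair, which lay closer together, and assumes that the lone array varies like it. camera called 13 lists, and 10 to 11 when an array was left out, 0 with an estimated correlation, 0 by fry and 8 under the header's grouping; it called 13 or 14 under each other alternative.

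The replicate numbers come from the labels, which do not say that they pair the cultures, and with 2 pairs the pairing cannot be settled. The deviations of same-numbered arrays correlated at 0.575 across genes, and at 0.385 with no detection filter. The replicate block moved the calls from 0 to 425, 277 higher and 148 lower, which include 59 of the 74 named genes, the features at an unadjusted p under 0.05 from 1065 to 2393, and the called lists not at all (13). Features at least 2-fold apart numbered 109, also on the deposited values without further normalization, and 225 without wild type replicate 2 (119 higher). From the raw signals, over 14426 features in place of 13786, they numbered 68 with no background correction and 147 with an offset of 50. With background correction at an offset of 16 they numbered 264 with cyclic loess, 249 with median scaling and 258 with neqc. These last counts were similar under each normalization, so they differed from 109 with the starting values and background correction more than with the normalization. The cause was not tested further. Features at an unadjusted p under 0.05 numbered 383 without mH2A1.2_KO replicate 1, 486 without mH2A1.2_KO replicate 2, 2026 without wild type replicate 2 and 1929 under the header's grouping.

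The header's grouping is the split by replicate number, independent by design of the split used, so signs can turn often whatever the group differences. Under the header's grouping the sign turned for 36 of 74 named genes and the direction of the list test for 16 of 25 lists. The log2 differences there were AKR1C2 -0.04, ANGPTL4 0.90, ANKRD1 -0.51, BTBD10 0.21, CDA -0.49, CDKN1A 0.15, CFB -0.56, CTSC 0.19, DDX43 0.09, DUSP1 -0.12, EGR1 0.89, F3 -0.32, H1-2 -0.59, H2AC20 -0.35, H2AC6 -0.88, H2AJ -0.45, IFIT1 -0.27, IGFBP4 -0.92, IL32 -0.19, IL6 -1.62, JDP2 -0.12, KRT8 -0.26, LTB -0.84, MACROH2A2 0.08, MCM10 0.44, MSMO1 -0.33, NOP16 0.70, PHLDA3 -0.16, PLAAT4 -0.06, PSMB9 -0.26, RPN2 0.10, RRM2 0.73, SNORA28 -0.01, SPP1 0.05, TKTL1 -0.08, VEGFA 0.08. The medians of those lists there were antigen presentation -0.31, cancer-testis antigens 0.027, cholesterol biosynthesis -0.12, DNA replication and S phase 0.36, epithelial adhesion and keratin genes -0.28, macroH2A and other H2A and H3 variants -0.052, mesenchymal genes -0.16, mitochondrial respiratory chain -0.039, MYC target and nucleolar genes 0.48, NF-kappaB target genes -0.14, NRF2 target genes and metallothioneins -0.041, p53 target genes 0.029, replication-dependent core histones -0.24, senescence-associated secreted factors -0.063, TGF-beta and YAP target genes -0.16, type I interferon response -0.027. Between the 2 arrays placed alike the sign turned for IL6 (-0.47), NOP16 (0.18), DNA replication (0.14), MYC targets (0.31), antigen presentation (-0.11) and mesenchymal genes (-0.039). The medians of osteoclast factors (-0.19) and of H2A and H3 variants (-0.034) also turned there, toward the test's direction. With no detection filter the medians were 0.065 for NF-kappaB targets, 0.17 for epithelial genes, 0.35 for core histones and 0.0049 for mesenchymal genes. Immediate early genes had -0.095 and the unfolded protein response -0.16 when detected on all 4 arrays. Other turns of a list's direction were p53 targets (-0.061 when detected on all 4 arrays, -0.039 with median scaling, -0.072 to 0.067 when an array was left out) and osteoclast factors (0.049 when detected on all 4 arrays and at a detection p under 0.05, 0.012 with the replicate block, -0.14 to 0.081 when an array was left out, turned without wild type replicate 1 and without mH2A1.2_KO replicate 2). When an array was left out, medians ran from -0.023 to 0.26 for G2 and mitosis and from -0.098 to 0.20 for heat shock proteins, lowest without wild type replicate 1, and from -0.38 to -0.0048 for DNA replication, -0.44 to 0.15 for MYC targets and -0.064 to 0.43 for antigen presentation, whose direction turned without wild type replicate 2. They ran from -0.047 to 0.23 for mesenchymal genes, -0.0031 to 0.17 for TGF-beta and YAP targets, -0.11 to 0.0086 for H2A and H3 variants, -0.28 to 0.041 for bone metastasis genes, -0.30 to -0.14 for cancer-testis antigens, -0.079 to -0.026 for ribosomal proteins, 0.02 to 0.079 for the respiratory chain, -0.27 to 0.02 for senescence factors and from -0.064 to 0.28 for heterochromatin proteins. Antigen presentation had 0.25 with cyclic loess and 0.22 with median scaling. Leaving out 1 array moved the difference by over 1.5 times for 25 of the 74 named genes, namely LTB, IFIT1, IGFBP4, EGR1, TMSB15A, NPTX2, LGMN and these, with their range: H2AJ 0.49 to 1.02, LMNB1 0.17 to 0.56, H2AC6 0.82 to 1.8, IL6 0.32 to 1.98, CCNB1 0.27 to 1.1, KIF20A 0.32 to 0.77, RRM2 -1.56 to -0.53, MCM10 -0.91 to -0.44, ANGPTL4 -1.59 to -0.63, GPI 0.39 to 1.1, ASNS -0.95 to -0.47, DNAJB4 0.16 to 0.57, BAG3 0.14 to 0.51, RPL28 -0.5 to -0.11, RPL8 -0.49 to -0.05, NDUFB10 0.19 to 0.67, NOP16 -1.02 to -0.01, NQO1 0.84 to 1.73. The cause was not tested. No alternative other than the header's grouping and the 2 arrays placed alike turned the sign of a named gene. The detection filter limits what dim probes can show, such as SPP1, which has no value when all 4 arrays must be above background. The 2 arrays placed alike give a difference with no test, so no count of features or lists.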

Other observations

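The interferon tests were set out before the results were seen; the tests on histone genes and small RNAs were chosen after. Small noncoding RNAs were chosen by symbol. Over 120 tested ones, 64 were higher in mH2A1.2_KO and the median log2 difference was 0.016, with a 95% bootstrap interval over genes of -0.044 to 0.083. The 3 highest were SNORA28 (1.62), SNORA2B (1.30) and SNORA80E (1.28) and the 2 lowest VTRNA1-1 (-0.80) and RNU4-1 (-0.66), with adjusted p-values of 0.250, 0.231, 0.360, 0.608 and 0.588, so none passed the test.

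Arrays of the same replicate number shared differences that cut across the groups. Replicate 1 minus replicate 2, averaged over both groups, had a median of -0.36 for DNA replication genes, -0.48 for MYC target and nucleolar genes, -0.21 for G2 and mitosis genes and 0.31 for antigen presentation genes. camera gave adjusted p-values of 4.53e-10, 4.53e-10, 1.78e-05 and 0.00372 in that order, none of which was under 0.05 with an estimated correlation. Splitting the arrays by replicate number gave 1929 features at an unadjusted p under 0.05, against 1065 for mH2A1.2_KO against wild type and 48 for the crossed split. limma called 0 features at an adjusted p under 0.05 in each of the 3 splits. The split by replicate number is also the grouping that the raw table's header gives.

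The higher interferon response genes were set against 2 technical explanations. A shift carried by 1 replicate pair would leave the list's median at 0.1 or less in the other pair, and the lower of the 2 pair medians was 0.34. A shift that depends on signal level would put the list's median among random lists matched on mean level, and it lay at percentile 100 of 10000 such lists. A response to the way the cells were depleted, or to macroH2A1 itself, may account for the pattern and was not tested. The median was 0.49 between the 2 arrays that both tables place alike, and -0.027 under the raw table's header.

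The higher core histone genes, whose transcripts mostly lack a poly(A) tail, were set against a higher yield of such transcripts in the labelled RNA. The test assumed that this would raise small noncoding RNAs as well, and their median of 0.016 lay below the 0.3 set for it. Whether small RNAs and histone transcripts were recovered and labelled alike was not tested. These RNAs went both ways, with 64 of 120 higher. Among the 15 with a mean log2 signal of at least 9 the median was 0.053. Of these 15, SNORD3D (1.27), SNORD3C (1.16) and SNORD3A (1.07) were highest, with arrays that did not overlap, and SNORD13 was lowest (-0.44). The medians go against a general rise of small noncoding RNAs, but cannot exclude a higher yield limited to some of them or to the histone transcripts. More cells in S phase could raise histone transcripts, and the DNA replication list had a median of -0.17. The rule for this test was made stricter after the values were seen, to ask for the same sign in all 4 differences between an array of each group. The median was -0.12 in the first replicate pair, -0.24 in the second and -0.52 for mH2A1.2_KO replicate 1 minus wild type replicate 2, where core histones had medians of 0.71, 0.58 and 1. Between wild type replicate 1 and mH2A1.2_KO replicate 2 the DNA replication median was 0.14, with 0.37 for core histones. The 4 differences come from the same 4 arrays and are not separate tests. The last 2 also hold the difference between replicate numbers, which was -0.36 for the DNA replication list (replicate 1 minus replicate 2). The 2 pair medians were negative, but the labels do not say that the numbers pair the arrays. The rule asked for the same sign in all 4 differences, so S phase stays open.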
